A study of Mus musculus with 12 samples.

How the data were processed

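RNA was measured in 12 libraries of hematopoietic stem cells (HSC) from the bone marrow of young adult C57BL6 mice. The cells were cultured for 4 h in a defined medium with stem cell factor and thrombopoietin at 50 ng/ml each, 2-mercaptoethanol at 50 µM and bovine serum albumin at 0.1%. Per the labels, RNA was extracted with a micro column kit and made into libraries by the SMARTseq2 protocol, which carries no molecular identifiers. The submitters name Bowtie 1.0.0, STAR 2.6.1, featureCounts 1.6.5 and the genome build GRCm38, without the role or order of each. The annotation release, the strand setting, the treatment of reads that map to several places and the way the cells were sorted are not given in the sources used here. The deposited table holds raw counts per gene, whole numbers for 23777 genes, with no normalization by the authors.

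Each library was placed in 1 of 4 groups of 3 by its labels: wild type or Hsf1-/-, with vehicle or with 17-AAG. Replicate numbers are those of the labels and run from 1 to 12 across the groups. The labels do not say whether replicates are separate mice, separate cultures or separate libraries of 1 culture, so the p-values measure the spread between these samples, which can be technical. No batch, animal or litter is given, so no block was fitted. Total counts ranged from 24884438 to 44258383 per library. Gene positions came from the reference annotation of the same build, in which 23641 of the 23777 gene identifiers matched with the version number removed, and 18102 with it.

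Genes were tested with edgeR 4.0.16 in R 4.3.3. Low counts were filtered with filterByExpr at a minimum count of 10, which left 15092 genes. Library sizes were scaled with TMM factors, which ranged from 0.947 to 1.05, and values per library are given as TMM-scaled CPM. A single quasi-likelihood fit with 4 group means and robust spread gave 7 comparisons: 17-AAG against vehicle in each genotype, genotype under each treatment, the interaction, and the average of each factor over the other. A gene was called at an adjusted p under 0.05 (Benjamini-Hochberg over the genes tested). The common biological coefficient of variation was 0.520, with 8 residual degrees of freedom. Log2 differences are given with their standard error (SE) and CPM with the standard deviation (SD).

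Genes were named by a rule fixed before the data were examined. In each comparison it takes up to 10 genes that rose and 10 that fell with the smallest p among called genes with a mean of at least 5 CPM. For comparisons of 2 groups the 3 libraries of one group must also lie above the 3 of the other, which chance gives for 10% of genes. Genes with only a predicted symbol were counted, not named. Hsf1 and a fixed set of heat-shock genes were always named, and so were up to 4 members with the smallest p of each list described. Any gene named outside this rule is said to have been chosen after its values were seen.

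A total of 34 gene lists, chosen in the same way from textbook knowledge, covered stress responses, metabolism, growth, the cell cycle, signalling and markers of other cell types. Of the listed genes, 12 were not in the table. Each list was tested against all other genes with camera (limma 3.58.1) at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 34 lists of a comparison. The same test was repeated with a correlation estimated from the data, and the list alone was tested with fry, a rotation test of whether its genes move one way on balance. Scores per library, the mean log2 CPM of a list, were compared with exact two-sided permutation tests. With 3 libraries against 3 the smallest p these can give is 0.1. The averaged comparisons permuted labels within the other factor.

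Alternatives were DESeq2 size factors and upper-quartile scaling, no filter and a filter at 5 CPM in 3 libraries, the DESeq2 1.42.0 Wald test, limma-voom with quality weights, a fit of only the groups compared, and leaving out each library in turn. A term for libraries with Y-linked transcripts, leaving out 2 chromosome segments, and leaving out libraries for the list tests were added after the data were seen. The pipeline was tested on simulated data of 15092 genes in which 200 genes per run were given known fold changes, in 5 runs. In the average over treatments it recovered 48.4% of genes changed 2-fold and 68.4% of those changed 4-fold. It recovered 31.2% and 60% for 17-AAG in wild-type cells, from 3 libraries against 3, and 10.8% and 47.6% for the interaction, which uses all 12 libraries. Over the 5 runs 29, 20 and 13 unchanged genes were called in these comparisons. A shift of 1.5-fold in the heat-shock list was called in 5 of 5 runs in each comparison. Unchanged lists were called in 5 of 155 tests for 17-AAG in wild-type cells, in 1 of 155 in cells labelled Hsf1-/- and in 0 of 155 in each of the other comparisons. Simulated genes varied independently of each other, so these list rates do not show how the test behaves where genes of a list vary together.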

Results

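The series measured RNA in 12 libraries of mouse HSC cultured for 4 h, in 4 groups of 3 libraries. Cells were wild type or labelled Hsf1-/-, and received 0.02% DMSO, the vehicle, or 5 nM 17-AAG, an inhibitor of the chaperone HSP90. Replicates 1, 2 and 3 are wild type with vehicle, and replicates 4, 5 and 6 are labelled Hsf1-/- with vehicle. Replicates 7, 8 and 9 are wild type with 17-AAG, and replicates 10, 11 and 12 are labelled Hsf1-/- with 17-AAG. Total counts per library ran from 28602034 to 29729413 in the wild-type vehicle libraries, 24884438 to 29292501 in the labelled Hsf1-/- vehicle libraries, 28019771 to 33062351 in the wild-type 17-AAG libraries and 27664947 to 44258383 in the labelled Hsf1-/- 17-AAG libraries. Each library had counts for 16394 to 17286 genes. Ftl1, the ferritin light chain, was the most abundant gene at a mean of 53305 CPM, and the 10 most abundant genes took 12.6% to 14.1% of counts. Mitochondrial transcripts took 0.462% to 0.749% of counts. Ribosomal RNA took 1.53 ± 0.167% (SD, n = 3) in labelled Hsf1-/- vehicle libraries, against 0.836 ± 0.244% in wild-type vehicle libraries, 1.16 ± 0.562% in wild-type 17-AAG libraries and 1.12 ± 0.180% in labelled Hsf1-/- 17-AAG libraries. In each group 1 library carried Y-linked transcripts: Ddx3y stood at 43.9 to 50.3 CPM in replicates 3, 6, 9 and 12. It was at most 1.25 CPM in the other 8 libraries, which had Xist at 18.2 to 37.3 CPM.

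Hsf1 itself, the transcription factor of the heat-shock response, was counted higher in the libraries labelled Hsf1-/-. Its level was 139.7 ± 10.7 CPM (SD, n = 6) in them and 74.1 ± 6.10 CPM (n = 6) in wild-type libraries, a ratio of 1.88. The ranges, 122 to 152 and 64.9 to 82.5 CPM, did not overlap (exact permutation test, two-sided, p = 0.00216 over 924 arrangements). This test, like the others of 6 libraries against 6, treats the 12 libraries as separate samples, which the labels do not state. The gene (ENSMUSG00000022556.9) lies on chromosome 15 of GRCm38, from 76477422 to 76501913. Hspa1a, the inducible HSP70 chaperone and a main target of HSF1, went the other way: 1.41 ± 1.15 CPM (n = 6) in libraries labelled Hsf1-/- and 17.6 ± 8.07 CPM (n = 6) in wild-type libraries. This is 12.5-fold lower, again without overlap (0.242 to 3.50 against 8.72 to 32.1 CPM, exact permutation p = 0.00216). Hspa1a (ENSMUSG00000091971.3) lies on chromosome 17 from 34969190 to 34972156. Its near-identical copy Hspa1b had 0.208 ± 0.151 CPM in wild-type libraries and 0.0114 ± 0.0179 CPM in those labelled Hsf1-/-, and how reads were shared between the copies is not given in the sources used here. The part of Hsf1 altered in the mutant is not given either. Without it, the higher counts over the whole gene neither bear out nor contradict the label. The groups are therefore called labelled Hsf1-/- throughout, and each direction is drawn by that label.

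**Figure D1:**
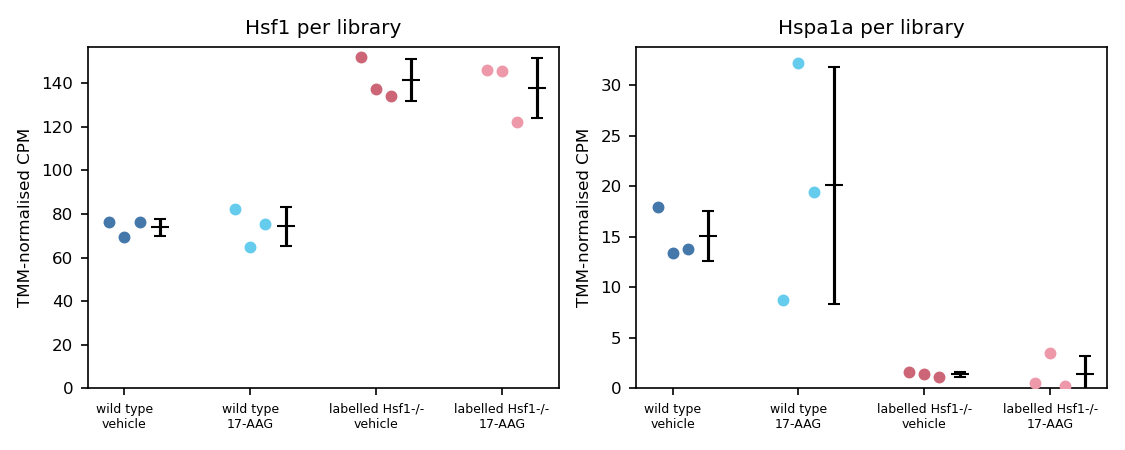
TMM-scaled CPM of Hsf1 and of Hspa1a in each of the 12 libraries (points), by group, with the mean and SD of the 3 libraries (bars; the vertical axes start at 0). Hsf1 lay between 122 and 152 CPM in the 6 libraries labelled Hsf1-/- and between 64.9 and 82.5 CPM in the 6 wild-type libraries, and Hspa1a was at most 3.50 CPM in the first and at least 8.72 CPM in the second.

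The response of wild-type cells to 17-AAG was compared first. None of the heat-shock genes that HSF1 is known to drive passed the test. Hspa8, the constitutive HSP70, was at 1696 ± 73.9 CPM (n = 3) with 17-AAG and 1608 ± 44.01 CPM (n = 3) with vehicle, a log2 difference of 0.08 (SE 0.18). Hsp90aa1 and Hsp90ab1, the cytosolic HSP90 genes and the target of the drug, differed by -0.08 (SE 0.12) and -0.07 (SE 0.07). Dnajb1, an HSP70 co-chaperone, stood at 200.2 ± 33.0 against 208 ± 35.6 CPM, and Bag3 at 123 ± 11.8 against 128 ± 2.62 CPM. Hspa1a was at 20.1 ± 11.7 against 15.1 ± 2.51 CPM (log2 0.42, SE 0.67). Of the 25 tested HSF1 target chaperones 0 rose and 0 fell, over all genes and adjusted over the list alone. The list median was -0.05 and the list adjusted p = 0.952. The smallest p in the list belonged to Stip1, an HSP90 co-chaperone, at 213 ± 22.9 against 270.2 ± 36.6 CPM (adjusted p = 1).

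Markers of T and NK cells fell as a list with 17-AAG in wild-type cells (adjusted p = 9.7e-06 with the preset correlation, adjusted p = 0.539 with an estimated correlation). All 11 tested members had negative differences with a median of -1.06, and 0 passed over all genes or adjusted over the list alone. Cd3e, a chain of the T cell receptor complex, was at 10.5 ± 8.11 CPM (n = 3) against 27.8 ± 14.9 CPM, and Trbc2, the constant region of the receptor beta chain, at 26.7 ± 14.5 against 44.5 ± 23.4 CPM. Nkg7, a granule protein of cytotoxic cells, was at 6.46 ± 6.57 against 17.1 ± 11.8 CPM. In vehicle replicates 1, 2 and 3 the score of the T and NK list was 3.98, 2.98 and 2.79. In drug replicates 7, 8 and 9 it was 2.15, 0.510 and 2.997, so the groups overlapped. Without wild-type 17-AAG replicate 8 the list's adjusted p was 0.0545. Macrophage markers fell as a list too (10 tested, adjusted p = 0.00343, adjusted p = 0.159 with an estimated correlation), with 0 members passing over all genes and 1 adjusted over the list alone. C1qc, the 1 that passed there, was at 0.0126 ± 0.0218 against 0.895 ± 1.10 CPM, and Spic at 0.314 ± 0.544 against 1.54 ± 0.157 CPM, both near the floor. The more abundant Axl, named after its values were seen, was at 36.2 ± 9.41 against 45.3 ± 12.2 CPM. The other 32 lists had adjusted p of 0.0994 or more, and some were called with 1 library left out. Cholesterol synthesis was then higher and G2 and M phase lower without replicate 3 (0.000305 and 3.07e-06) or 7 (0.00309 and 0.00468). Cytosolic ribosomal proteins were lower without replicates 2 (0.00292), 3 (0.00197) or 7 (0.0270) and higher without replicate 1 (0.0328). Granulocyte and monocyte markers were lower without replicates 1 (0.0485) or 7 (0.0270), and multipotent progenitor markers without 7 (0.0130).

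Across all genes edgeR called 0 of 15092 in wild-type cells under 17-AAG. At an unadjusted p under 0.05 there were 655, where chance gives 755. DESeq2 and limma-voom also called 0. Among the 9276 genes with a mean of at least 5 CPM, the 95% interval excluded a change of 2-fold or more for 79.7%.

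In the cells labelled Hsf1-/- none of the heat-shock genes passed with 17-AAG either. Hspa8 was at 1173 ± 329.8 CPM (n = 3) with the drug and 1232 ± 315 CPM (n = 3) with vehicle, a log2 difference of -0.07 (SE 0.18). Hsp90aa1 was at 541 ± 36.2 against 477 ± 54.1 CPM (0.18, SE 0.12). Hsph1, an HSP70 exchange factor, was at 34.1 ± 2.98 against 42.4 ± 11.3 CPM (-0.32, SE 0.17), and Hspa1a was at 1.43 ± 1.80 against 1.39 ± 0.228 CPM. The 25 HSF1 target chaperones had a median of -0.01 and a list adjusted p = 0.930, with 0 members passing over all genes and 0 adjusted over the list alone.

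T and NK cell markers fell as a list in these cells too (adjusted p = 7.12e-08, adjusted p = 0.977 with an estimated correlation). Of 11 members 10 had negative differences, with a median of -0.9998. None passed over all genes, and 2 fell when adjusted over the list alone. These were Lck, the T cell receptor kinase, at 47.0 ± 7.16 against 81.0 ± 8.73 CPM (n = 3 each, log2 -0.79, SE 0.19), and Cd3e at 4.93 ± 1.18 against 19.1 ± 1.22 CPM (-1.96, SE 0.62). The list score was lower in all 3 drug libraries than in all 3 vehicle libraries (exact permutation p = 0.1, the smallest that 3 against 3 allow). Cytosolic ribosomal proteins rose as a list by a median of 0.11 (33 of 40 positive, 0 passing over all genes or adjusted over the list alone, adjusted p = 0.000388, adjusted p = 0.977 with an estimated correlation). Rpl28, with the smallest p of that list, was at 289.5 ± 36.1 against 232 ± 6.04 CPM. The ribosomal list had an adjusted p of 0.0999 without labelled Hsf1-/- vehicle replicate 4 and 0.213 without labelled Hsf1-/- 17-AAG replicate 10. Lists called with 1 library left out were NRF2 targets, lower without replicates 4 (0.00728) or 11 (6.94e-05), and the interferon response, higher without 6 (0.00283) or 10 (0.0135) and lower without 12 (0.0167). G2 and M phase was higher without 11 (0.0457), and mast cell and basophil markers were lower without 12 (0.0107). Across all genes edgeR called 0 of 15092, with 603 at an unadjusted p under 0.05. DESeq2 called 9 (6 higher and 3 lower) and limma-voom 0.

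Averaged over both genotypes, with 6 drug libraries against 6 vehicle libraries, the heat-shock genes had narrower intervals around small differences. Hspa8 differed by 0.00 (SE 0.13), at 1435 ± 358 CPM (n = 6) against 1420.2 ± 288 CPM (n = 6). Hsp90aa1 differed by 0.05 (SE 0.08), Hsp90ab1 by -0.02 (SE 0.05), Dnajb1 by -0.02 (SE 0.11) and Hsph1 by -0.20 (SE 0.12). Bag3, Hspd1, Chordc1 and Ahsa1 differed by -0.04 (SE 0.07), 0.02 (SE 0.07), 0.08 (SE 0.09) and 0.01 (SE 0.06). Dnaja1, Hspb1 and Hspe1 differed by -0.08 (SE 0.09), -0.10 (SE 0.22) and -0.06 (SE 0.14). Hspa1a, the least precise, differed by 0.21 (SE 0.50, 95% interval -0.86 to 1.29). The HSF1 target list had an adjusted p of 0.950, with 0 members passing over all genes and 0 adjusted over the list alone. Hsf1 itself was at 106 ± 36.4 against 108 ± 37.5 CPM (-0.01, SE 0.08).

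**Figure D2:**
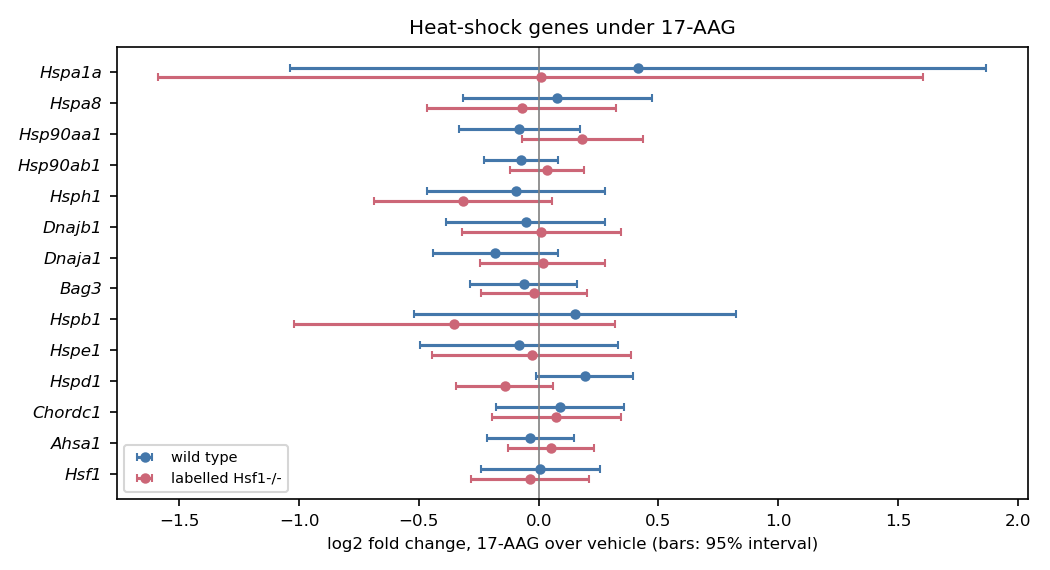
Log2 difference between 17-AAG and vehicle of Hsf1 and 13 heat-shock genes in wild-type cells (blue) and in cells labelled Hsf1-/- (red), from 3 libraries per group. Points are edgeR estimates and bars their 95% intervals, and none of these genes passed the test in either genotype.

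T and NK cell markers fell in this average (adjusted p = 5.5e-13, adjusted p = 0.179 with an estimated correlation). All 11 members had negative differences, with a median of -1.03. Over all genes 0 passed, and adjusted over the list alone 6 fell, among them Cd3e at 7.69 ± 6.003 against 23.4 ± 10.6 CPM (n = 6 each, log2 -1.68, SE 0.44) and Lck at 55.0 ± 11.3 against 73.8 ± 14.7 CPM (-0.43, SE 0.13). Trbc2 was at 19.6 ± 12.1 against 35.0 ± 18.1 CPM. The list score differed by -1.22 (exact permutation p = 0.015). Macrophage markers fell as a list (adjusted p = 0.0124, adjusted p = 0.179 with an estimated correlation), with 0 members passing over all genes or adjusted over the list alone. Axl, the most abundant of the 4 with the smallest p, was at 36.0 ± 8.61 against 44.7 ± 10.7 CPM. The macrophage list had an adjusted p of 0.0872 without wild-type vehicle replicate 2 and 0.0568 without wild-type 17-AAG replicate 7. With 1 library left out cholesterol synthesis was called as higher without replicates 3 (0.000628), 7 (0.00410) or 8 (0.0233), and cytosolic ribosomal proteins without 1 (6.36e-07) or 8 (0.0184). Called as lower were G2 and M phase without 3 (0.0160), granulocyte and monocyte markers without 5 (0.0211), NRF2 targets without 11 (0.0193) and mast cell and basophil markers without 12 (0.0105).

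Across all genes edgeR called 0 of 15092 for the average response, with 672 at an unadjusted p under 0.05. The interval excluded a 2-fold change for 93.9% of the 9276 genes at 5 CPM or more. DESeq2 called 4 and limma-voom 0. The 4, named after their values were seen, were Car11, Pdcd1, Dus2 and Rln3, with mean levels of 0.849, 18.3, 4.79 and 5.48 CPM.

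Whether the response to 17-AAG differed by genotype was tested with the interaction. Among heat-shock genes Hspa1a differed between genotypes by -0.41 (SE 0.996), with the response in wild-type cells the larger in value. The HSF1 target chaperones had a list adjusted p of 0.897, with 0 of 25 members passing over all genes or adjusted over the list alone. Cytosolic ribosomal proteins were the 1 list called: their response was higher in cells labelled Hsf1-/- by a median of 0.13, with 27 members positive and 13 negative (adjusted p = 0.0013, adjusted p = 0.959 with an estimated correlation). None of its 40 members passed over all genes or adjusted over the list alone. Its adjusted p was 0.688 without wild-type vehicle replicate 1, 0.149 without wild-type 17-AAG replicate 8 and 0.0754 without labelled Hsf1-/- 17-AAG replicate 10. The other lists had adjusted p of 0.124 or more. With 1 library left out G2 and M phase was called as higher without replicates 3 (6.36e-05), 4 (0.0191), 7 (0.0138) or 11 (0.00213), macrophage markers without 1 (0.0337) or 9 (0.0346) and the interferon response without 6 (0.0417). NRF2 targets were called as lower without 4 (0.0399) or 11 (0.00255), and the proteasome without 4 (0.0399). Across all genes edgeR called 0 of 15092, with 639 at an unadjusted p under 0.05 and limma-voom at 0. DESeq2 called 2, 4930451G09Rik and Gpr153, named after their values were seen, with means of 0.529 and 0.554 CPM. The interval of the interaction excluded a 2-fold difference for 59.4% of the 9276 genes at 5 CPM or more.

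The genotypes were compared under vehicle next, which addresses what the label Hsf1-/- changes in cultured cells. Of 15092 genes edgeR called 5 that were higher and 11 that were lower in the libraries labelled Hsf1-/-, with 1217 at an unadjusted p under 0.05. Besides Hsf1 (log2 0.94, SE 0.12, adjusted p = 0.00448), Rpl3-ps1 rose 2.69-fold to 63.2 ± 0.934 CPM from 23.5 ± 2.198 CPM (n = 3 each, adjusted p = 0.00279). Ly6k, a surface protein of the Ly6 family, rose 9.35-fold to 12.8 ± 3.798 from 1.36 ± 0.971 CPM (adjusted p = 0.0471). Tcn2, the vitamin B12 carrier transcobalamin, rose 3.03-fold to 54.9 ± 15.1 from 18.1 ± 6.18 CPM (adjusted p = 0.0262), and Nudcd3, an HSP90 co-chaperone, rose 1.64-fold to 141 ± 21.4 from 86.3 ± 5.60 CPM (adjusted p = 0.0284).

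Among the genes that fell under vehicle, Rabl2, a small GTPase, was 4.56-fold lower at 6.03 ± 1.21 against 27.6 ± 4.69 CPM (n = 3 each, adjusted p = 0.00274). Rpl3, a ribosomal protein, was 2.59-fold lower at 207 ± 14.5 against 536 ± 118 CPM (adjusted p = 0.00274). Its pseudogene Rpl3-ps1 on chromosome X is 99.8% identical over 1210 bases with 2 mismatches, so short reads can move between the pair. Apobec3, an antiviral cytidine deaminase, was 2.14-fold lower at 97.8 ± 16.2 against 209 ± 17.9 CPM. Tinagl1, Tmem184b, Lgals3, Pes1, Tgm2 and Cap1 were 1.65-fold, 2.13-fold, 2.36-fold, 1.57-fold, 1.90-fold and 3.33-fold lower, with adjusted p from 0.00877 to 0.0348. Of these, Lgals3 encodes galectin-3, Tgm2 a transglutaminase, Pes1 a ribosome assembly factor and Cap1 a regulator of actin. Actb, cytoplasmic actin, was 1.37-fold lower at 21964 ± 1542 against 30129 ± 321 CPM (adjusted p = 0.0447). The remaining gene, Gm13453, has a predicted symbol and is named here after its values were seen. Hspa1a was at 1.39 ± 0.228 against 15.1 ± 2.51 CPM (log2 -3.43, SE 0.76), with an adjusted p of 0.204 in edgeR, 0.0198 in edgeR with only these 2 groups fitted, and 0.000252 in DESeq2. DESeq2 called 106 genes and limma-voom 15. With any 1 of the 6 libraries left out edgeR called 6 to 10 genes, and without the genes of 2 chromosome segments on chromosomes 15 and 11 it called 4.

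Interferon-response genes fell as a list under vehicle (adjusted p = 4.88e-13, adjusted p = 0.473 with an estimated correlation), with 25 of 26 negative and a median of -0.42. None passed over all genes and 4 fell adjusted over the list alone. Bst2, an antiviral membrane protein, was at 183 ± 30.4 against 266 ± 14.5 CPM (n = 3 each), Irf7, a transcription factor of the response, at 144 ± 26.0 against 250.6 ± 28.9 CPM, and Isg15, a ubiquitin-like modifier, at 36.6 ± 9.04 against 59.4 ± 4.71 CPM. Genes of cholesterol synthesis fell as a list (adjusted p = 1.76e-09, adjusted p = 0.473 with an estimated correlation), with 18 of 20 negative, a median of -0.33, 0 passing over all genes and 9 lower adjusted over the list alone. Dhcr7, the last enzyme of the pathway, was at 117 ± 12.7 against 333 ± 129.8 CPM (adjusted p = 0.0948), and Fdft1, squalene synthase, at 477 ± 25.1 against 691 ± 123 CPM. HSF1 target chaperones fell as a list (adjusted p = 0.00804, adjusted p = 0.473 with an estimated correlation), with 18 of 25 negative and a median of -0.14, 0 passing over all genes and 1 adjusted over the list alone. That call was lost without labelled Hsf1-/- vehicle replicate 4 (adjusted p = 0.105). Hspa8 was at 1232 ± 315 against 1608 ± 44.01 CPM, and Stip1 at 220.5 ± 17.4 against 270.2 ± 36.6 CPM.

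Cytokine signalling feedback genes fell as a list under vehicle (adjusted p = 0.000218, adjusted p = 0.473 with an estimated correlation), with 16 of 21 negative and 3 lower adjusted over the list alone. These were Ccnd2 and Ccnd3, D-type cyclins, at 605 ± 42.4 against 791 ± 91.5 CPM and 609 ± 85.9 against 838 ± 97.5 CPM, and Cish, an inhibitor of STAT5 signalling, at 952 ± 62.9 against 1274 ± 104 CPM (n = 3 each). Cytosolic ribosomal proteins fell (35 of 40 negative, adjusted p = 1.91e-09, adjusted p = 0.483 with an estimated correlation), with Rpl3 the 1 member that passed. The mean log2 score of this list was 9.38, 8.97 and 8.98 in replicates 1, 2 and 3. It was 8.83, 8.97 and 8.86 in replicates 4, 5 and 6, so replicate 1 carried much of the difference. Immediate early genes (16 of 20 negative, adjusted p = 0.000912), the integrated stress response (18 of 25 negative, adjusted p = 0.0167) and TRiC and prefoldin (13 of 14 negative, adjusted p = 0.0385) fell as lists. Genes of S phase rose as a list (20 of 22 positive, adjusted p = 0.00804), with Slbp, the histone mRNA binding protein, at 128 ± 3.38 against 106 ± 1.67 CPM. Each of these last 4 lists had an adjusted p of 0.483 with an estimated correlation, and 0 members passed over all genes or adjusted over the list alone. Without labelled Hsf1-/- vehicle replicate 4 their adjusted p values were 0.105, 0.176, 0.195 and 0.0986. The call of the integrated stress response was also lost without wild-type vehicle replicate 3 (0.126), and that of TRiC and prefoldin without replicates 2 (0.0558), 3 (0.0783) or 6 (0.0890). Lists gained with 1 library left out were T and NK cell markers, lower without replicates 2 (0.0368) or 3 (0.00452), glycolysis, lower without 1 (0.0409), 3 (0.0469) or 4 (0.0415), and the ER unfolded protein response, lower without 1 (0.0409) or 4 (0.0326). Actin and SRF-MRTF targets were lower without 2 (0.0368), oxidative phosphorylation without 3 (0.0129), and G2 and M phase was higher without 1 (0.0137). Ribosomal RNA took a larger share in the labelled Hsf1-/- vehicle libraries (1.53 ± 0.167% against 0.836 ± 0.244%, n = 3 each).

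Under 17-AAG, in libraries not used for the vehicle comparison, edgeR called 5 genes higher and 8 lower in cells labelled Hsf1-/-, with 1142 at an unadjusted p under 0.05. Hsf1 rose by 0.89 (SE 0.12, adjusted p = 0.0102), to 138 ± 13.7 from 74.3 ± 8.86 CPM (n = 3 each). Rpl3-ps1 rose 2.203-fold and Ly6k 10.9-fold, to 12.9 ± 2.79 from 1.19 ± 0.635 CPM (adjusted p = 0.0176 and 0.0441). Cd34, a sialomucin of progenitor cells, rose 1.84-fold to 116 ± 8.86 from 62.9 ± 7.54 CPM, and Hist1h1c, a linker histone, 1.88-fold to 97.2 ± 4.20 from 51.6 ± 10.3 CPM (both adjusted p = 0.0458). Rabl2 was 5.31-fold lower at 6.36 ± 1.02 against 33.8 ± 2.33 CPM (adjusted p = 0.00108). Tinagl1, Apobec3, Pes1, Tgm2, Cap1 and Ccm2 were 1.77-fold, 1.96-fold, 1.64-fold, 1.89-fold, 3.40-fold and 1.71-fold lower, with adjusted p from 0.00526 to 0.0496. Ccm2 encodes a scaffold of the cerebral cavernous malformation complex. The last of the 8, Gm13453, is named after its values were seen. Rpl3 was at 261 ± 18.3 against 443 ± 81.3 CPM (log2 -0.76, adjusted p = 0.125). Hspa1a was at 1.43 ± 1.80 against 20.1 ± 11.7 CPM (log2 -3.84, SE 0.77), with an adjusted p of 0.125 in edgeR, 0.00768 in edgeR without labelled Hsf1-/- replicate 11, and 1.33e-05 in DESeq2. DESeq2 called 98 genes and limma-voom 9. With 1 of the 6 libraries left out edgeR called 3 to 10 genes, and without the genes of the same segments it called 3.

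Interferon-response genes fell as a list under 17-AAG as well (adjusted p = 7.71e-12, adjusted p = 0.338 with an estimated correlation), with 25 of 26 negative, a median of -0.38, 0 passing over all genes and 3 lower adjusted over the list alone. Bst2 was at 169.7 ± 16.2 against 272 ± 18.4 CPM (n = 3 each) and Oas1a, an antiviral synthetase, at 109 ± 22.7 against 169 ± 40.1 CPM. Cholesterol synthesis fell as a list (adjusted p = 1.4e-10, adjusted p = 0.338 with an estimated correlation), with 20 of 20 negative, a median of -0.29, 0 passing over all genes and 6 lower adjusted over the list alone. Dhcr7 was at 128 ± 14.6 against 355 ± 148 CPM and Lss, lanosterol synthase, at 325 ± 59.9 against 480.1 ± 51.3 CPM. HSF1 target chaperones fell as a list (adjusted p = 0.0194, adjusted p = 0.338 with an estimated correlation), with 18 of 25 negative, a median of -0.08, 0 passing over all genes and 1 adjusted over the list alone. Without wild-type 17-AAG replicate 9 that adjusted p was 0.109. Hspa8 was at 1173 ± 329.8 against 1696 ± 73.9 CPM.

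Genes of G2 and M phase rose as a list under 17-AAG (19 of 22 positive, median 0.59, adjusted p = 0.00037, adjusted p = 0.568 with an estimated correlation). Bub1b, a spindle checkpoint kinase, was at 11.3 ± 0.158 against 4.30 ± 2.54 CPM and Ccna2, cyclin A2, at 45.3 ± 8.70 against 28.8 ± 4.49 CPM (n = 3 each). None passed over all genes or adjusted over the list alone. Lists of TRiC and prefoldin (13 of 14 negative, adjusted p = 0.0132), cytokine signalling feedback (14 of 21 negative, adjusted p = 0.0109, 1 lower adjusted over the list alone) and immediate early genes (14 of 20 negative, adjusted p = 0.0255) fell, each with an adjusted p of 0.568 with an estimated correlation. Osm, the cytokine oncostatin M, was at 38.9 ± 6.10 against 78.4 ± 17.8 CPM. Proteasome genes (25 of 32 negative, adjusted p = 0.0225) and T and NK cell markers (9 of 11 negative, adjusted p = 0.0258) fell, each with an adjusted p of 0.638 with an estimated correlation. Macrophage markers rose as a list (adjusted p = 0.0132, adjusted p = 0.338 with an estimated correlation), with Spic, a member near the floor, at 4.26 ± 0.296 against 0.314 ± 0.544 CPM and the more abundant Axl, named after its values were seen, at 35.7 ± 9.82 against 36.2 ± 9.41 CPM. Without wild-type 17-AAG replicate 9 the adjusted p was 0.171 for TRiC and prefoldin, 0.357 for cytokine feedback, 0.407 for immediate early genes and 0.739 for T and NK markers. The last list was also lost without replicates 7 (0.0946), 11 (0.0708) or 12 (0.0933), immediate early genes without 10 (0.495) or 12 (0.0703), and the proteasome without 7 (0.264), 10 (0.105) or 12 (0.0617). Lists gained were S phase, higher without replicates 7 (0.00244) or 12 (0.0361), granulocyte and monocyte markers, higher without 7 (0.0442) or 12 (0.0361), and p53 targets, higher without 10 (0.0285). Called as lower were the ER unfolded protein response without 8 (0.04700) or 10 (0.0260), the integrated stress response without 8 (0.0219) or 12 (0.0404), cytosolic ribosomal proteins without 8 (0.0107) or 10 (0.0260), ribosome biogenesis without 10 (0.0285) and NRF2 targets without 11 (2.53e-05).

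The genotype comparisons under vehicle and under 17-AAG share no libraries, and the labels do not say whether vehicle and 17-AAG libraries came from the same animals. The expected numbers given here hold for separate animals. Hsf1, Ly6k and Rpl3-ps1 were higher in both, 3 genes where independent lists would share 0.00166. Apobec3, Cap1, Gm13453, Pes1, Rabl2, Tgm2 and Tinagl1 were lower in both, 7 genes where 0.00583 would be shared. Across the 9276 genes at 5 CPM or more, the genotype differences under vehicle and under 17-AAG had a Pearson correlation of 0.457. The 17-AAG differences in the 2 genotypes had one of 0.0748. Both are across genes, which are not independent replicates.

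Averaged over treatments, with 6 libraries against 6, edgeR called 14 genes higher and 65 lower in cells labelled Hsf1-/-, 7 of them with predicted symbols, and 1709 had an unadjusted p under 0.05. Hsf1 (log2 0.91, SE 0.08) and Rpl3-ps1 (1.28, SE 0.12) rose with an adjusted p of 0.000106 each. Ly6k rose 10.1-fold to 12.9 ± 2.98 from 1.28 ± 0.740 CPM (n = 6 each), Tcn2 2.39-fold to 52.6 ± 10.3 from 22.4 ± 6.32 CPM, and Cd34 1.67-fold to 110.2 ± 15.8 from 65.9 ± 6.22 CPM. Nudcd3, Gas2l3, a microtubule and actin linker, Hist1h1c, Eprs, the glutamyl-prolyl tRNA synthetase, and Rasd2, a small GTPase, rose 1.55-fold, 1.68-fold, 1.54-fold, 1.41-fold and 2.46-fold. Rabl2 was 4.92-fold lower at 6.20 ± 1.01 against 30.7 ± 4.77 CPM (adjusted p = 2.66e-05). Dhcr7 was 2.81-fold lower at 123 ± 13.5 against 344 ± 125 CPM (adjusted p = 0.00352), Lgals3 2.21-fold lower at 80.0 ± 8.46 against 176 ± 34.8 CPM and Tgm2 1.90-fold lower at 1709.8 ± 255 against 3243 ± 332 CPM (both adjusted p = 0.000732). Apobec3, Tinagl1, Pes1, Rpl3, Cap1 and Tmem184b were 2.05-fold, 1.71-fold, 1.61-fold, 2.09-fold, 3.37-fold and 1.83-fold lower, with adjusted p from 0.000106 to 0.00178. DESeq2 called 333 genes and limma-voom 93. With 1 library left out edgeR called between 34 (without replicate 5) and 101 (without replicate 1), without the segments 43, and with a term for Y-linked transcripts 148.

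Of the main heat-shock chaperones, Hspa1a alone passed with edgeR in this average. Hspa1a fell by 3.64 on the log2 scale (SE 0.54, adjusted p = 0.00845). Hspa8 was at 1202 ± 290.5 CPM (n = 6) in cells labelled Hsf1-/- and 1652 ± 72.8 CPM (n = 6) in wild-type cells (-0.46, SE 0.13, adjusted p = 0.178). The adjusted p of Hspa8 was 0.0232 in DESeq2, 0.0328 with a term for Y-linked transcripts and 0.0426 without labelled Hsf1-/- 17-AAG replicate 12. Dnajb1 was at 169 ± 18.6 against 204 ± 31.0 CPM (-0.27, SE 0.11). Hsph1, Chordc1, Hspe1, Dnaja1 and Ahsa1 differed by -0.28, -0.17, -0.11, -0.09 and -0.07. Hsp90ab1, Hspb1 and Bag3 differed by -0.08, -0.08 and -0.05, and Hsp90aa1 and Hspd1 by 0.14 and 0.05. As a list the 25 HSF1 target chaperones fell (adjusted p = 0.00125, adjusted p = 0.260 with an estimated correlation), with 20 negative, a median of -0.09, 1 member passing over all genes and 2 adjusted over the list alone. The list score was lower by -0.29 (exact permutation p = 0.005).

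Interferon-response genes fell in the average over treatments (25 of 26 negative, median -0.40, adjusted p = 1.61e-18, adjusted p = 0.260 with an estimated correlation). Over all genes 3 passed and fell, and 15 did adjusted over the list alone. They were Bst2 at 176 ± 23.0 against 269 ± 15.2 CPM (n = 6 each, adjusted p = 0.00414), Irf7 at 143 ± 31.7 against 246 ± 43.1 CPM and Irf9, a partner of STAT1 and STAT2, at 134 ± 12.1 against 181 ± 19.7 CPM (both adjusted p = 0.0445). The list score, a mean log2 CPM, was 6.75 to 6.89 in the 6 wild-type libraries. It was 6.14, 6.10, 6.004 and 6.33 in replicates 4, 5, 10 and 11, and 6.72 and 6.58 in replicates 6 and 12. The exact permutation test of the genotypes gave p = 0.005. Replicates 6 and 12 carry Y-linked transcripts, but so do wild-type replicates 3 and 9, which scored 6.85 and 6.80. Gm26825, named after its values were seen, split the labelled libraries alike. It was at 75.1, 101, 88.4 and 92.9 CPM in replicates 4, 5, 10 and 11 and at 0.567 and 0.749 CPM in 6 and 12. The cause of this split was not tested. Cholesterol synthesis fell (18 of 20 negative, median -0.30, adjusted p = 8.83e-15, adjusted p = 0.260 with an estimated correlation). Dhcr7 and Fdft1 passed over all genes and 12 members adjusted over the list alone. Fdft1 was at 504 ± 41.1 against 710.1 ± 115 CPM and Lss, which did not pass, at 311 ± 46.5 against 442 ± 65.7 CPM.

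**Figure D3:**
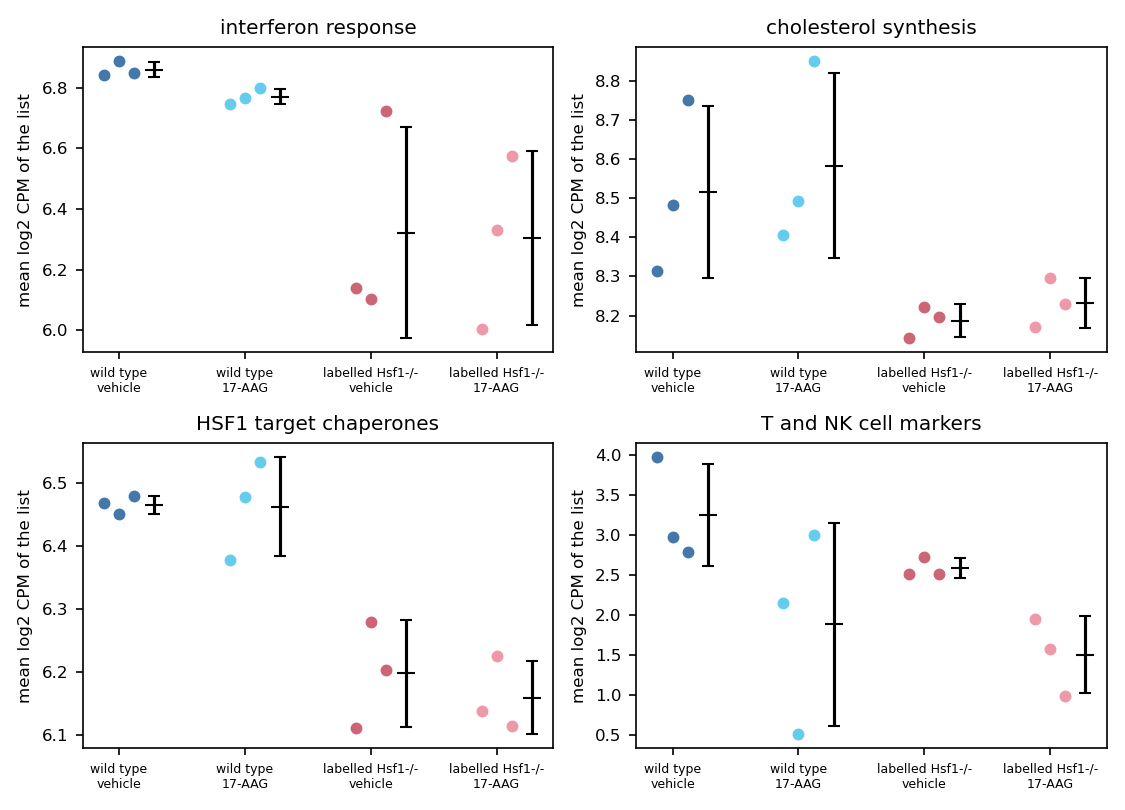
Mean log2 CPM of the interferon-response, cholesterol-synthesis, HSF1-target and T and NK cell lists in each of the 12 libraries (points), by group, with the mean and SD of the 3 libraries (bars; each axis spans only the values shown). Interferon scores were 6.75 to 6.89 in wild-type libraries and 6.004 to 6.72 in those labelled Hsf1-/-, and T and NK scores ranged from 0.510 in replicate 8 to 3.98 in replicate 1.

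Cytokine signalling feedback fell over both treatments (16 of 21 negative, adjusted p = 4.85e-05, adjusted p = 0.294 with an estimated correlation). Osm, Ccnd2 and Cish passed over all genes and 9 members adjusted over the list alone. Osm was at 49.8 ± 13.7 against 87.4 ± 27.1 CPM (n = 6 each), Ccnd2 at 635 ± 47.4 against 798 ± 62.3 CPM and Cish at 963 ± 52.4 against 1237 ± 133 CPM. Cytosolic ribosomal proteins fell (39 of 40 negative, median -0.13, adjusted p = 1.14e-05, adjusted p = 0.530 with an estimated correlation), with Rpl3 the 1 member passing over all genes and the 1 adjusted over the list alone. The score of this list was 9.38 in replicate 1 and 8.93 to 9.10 in the other wild-type libraries. It was 8.83 to 9.11 in the labelled libraries. Immediate early genes (17 of 20 negative, adjusted p = 0.000417), TRiC and prefoldin (13 of 14 negative, adjusted p = 0.00301) and the integrated stress response (17 of 25 negative, adjusted p = 0.0067) fell as lists, each with an adjusted p of 0.321 with an estimated correlation. No member of these 3 lists passed over all genes, and 0, 1 and 2 did adjusted over the list alone. Socs3, an inhibitor of cytokine signalling, was at 216 ± 52.1 against 375 ± 150.3 CPM, Cct3, a TRiC subunit, at 439 ± 23.1 against 513 ± 32.7 CPM, and Trib3, a stress pseudokinase, at 255 ± 18.2 against 357 ± 71.7 CPM. Ribosome biogenesis fell weakly as a list (19 of 25 negative, adjusted p = 0.0482, adjusted p = 0.472 with an estimated correlation). Its 1 member that passed was Pes1, and its adjusted p was 0.0942, 0.0892, 0.113, 0.0709, 0.0705 and 0.192 without replicates 1, 3, 6, 7, 8 and 12.

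Cell-cycle lists rose over both treatments: S phase with 18 of 22 positive (adjusted p = 0.00335, adjusted p = 0.342 with an estimated correlation) and G2 and M phase with 19 of 22 positive (adjusted p = 0.00496, adjusted p = 0.530 with an estimated correlation). No member of either passed over all genes or adjusted over the list alone. Mcm5, a subunit of the replicative helicase, was at 165 ± 9.04 against 144 ± 14.9 CPM (n = 6 each) and Ccna2 at 47.4 ± 9.16 against 34.2 ± 9.41 CPM. The G2 and M list had an adjusted p of 0.0905 without replicate 3 and 0.0526 without replicate 10. T and NK cell markers fell (11 of 11 negative, adjusted p = 0.00999, adjusted p = 0.530 with an estimated correlation), with Trbc2 at 19.1 ± 7.48 against 35.6 ± 19.9 CPM and an adjusted p of 0.137 without replicate 1 and 0.187 without replicate 9. Macrophage markers rose (7 of 10 positive, adjusted p = 0.0342, adjusted p = 0.260 with an estimated correlation, 0.0582 without replicate 1), with Spic, a member near the floor, at 3.52 ± 1.21 against 0.928 ± 0.762 CPM. No member of these marker lists passed over all genes or adjusted over the list alone.

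The remaining lists were not called in the average over treatments. With 1 library left out the ER unfolded protein response was called as lower without replicates 1, 2, 4, 8, 10 or 12 (0.0147 to 0.0482), the proteasome without 3, 5, 6, 8, 9 or 11 (0.0309 to 0.0486), oxidative phosphorylation without 2, 3 or 10 (0.0138 to 0.0444) and NRF2 targets without 5 (0.0427) or 11 (0.00482), and granulocyte and monocyte markers as higher without 5 (0.0425). HSC identity had an adjusted p of 0.158, although Mllt3, a chromatin reader of the stem cell state, fell by 1.22 (SE 0.19, adjusted p = 0.0127) to 24.9 ± 7.03 from 57.2 ± 13.9 CPM (n = 6 each). Esam and Hlf, further HSC genes, were at 353 ± 42.5 against 260.2 ± 36.5 CPM and 45.2 ± 8.75 against 27.5 ± 8.11 CPM and did not pass. Actin and SRF-MRTF targets had an adjusted p of 0.124, with Actb lower (adjusted p = 0.0168) at 23260.0 ± 1728 against 29102 ± 2263 CPM. HSP90 co-chaperones had an adjusted p of 0.486, with Nudcd3 the 1 member that passed, and multipotent progenitor markers one of 0.522, with Cd34 the 1 that passed. Adjusted p was 0.0725 for oxidative phosphorylation, 0.0756 for the ER unfolded protein response, 0.0802 for the proteasome, 0.124 for glycolysis, 0.230 for autophagy and lysosome, 0.426 for NRF2 targets, 0.486 for p53 targets, 0.486 for NF-kB targets and 0.994 for mitochondrial chaperones. Among markers it was 0.124 for granulocytes and monocytes, 0.751 for erythroid cells, 0.751 for mast cells and basophils, 0.806 for endothelium and stroma, 0.871 for B cells and 0.994 for megakaryocytes. Mitochondrial transcripts had 0.486 and sex-linked genes 0.841.

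The 79 genes called by genotype were not spread evenly over the genome. On chromosome 15, 8 of the 307 tested genes within 20 Mb of Hsf1 were called, where 1.61 would be by chance (odds ratio 5.53, 95% interval 2.28 to 11.6, Fisher's exact p = 0.000203). They were Hsf1, Ly6k (74796874 to 74799986), Rabl2 (89582533 to 89591923), Apobec3 (79891659 to 79915906), Rpl3 (80077791 to 80091868), Tmem184b (79360684 to 79403569), Tomm22 and Cbx7. In the first 10 Mb of chromosome 11, 8 of 86 tested genes were called, where 0.451 would be by chance. They were Tcn2 (3917192 to 3932159), Pes1 (3963975 to 3980004), Nudcd3 (6105691 to 6200415), Ccm2 (6546887 to 6596744), Osm, Mrps24, Dbnl and 8430429K09Rik. Tomm22, Cbx7, Mrps24, Dbnl and 8430429K09Rik are named after their values were seen. Cbx7 overlaps the end of Apobec3, and the strand setting of the counts is not given. The other 63 calls lay elsewhere, among them Dhcr7 on chromosome 7 (143823145 to 143848410), Hspa1a on chromosome 17 and Tinagl1 on chromosome 4 (130164454 to 130175122).

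**Figure D4:**
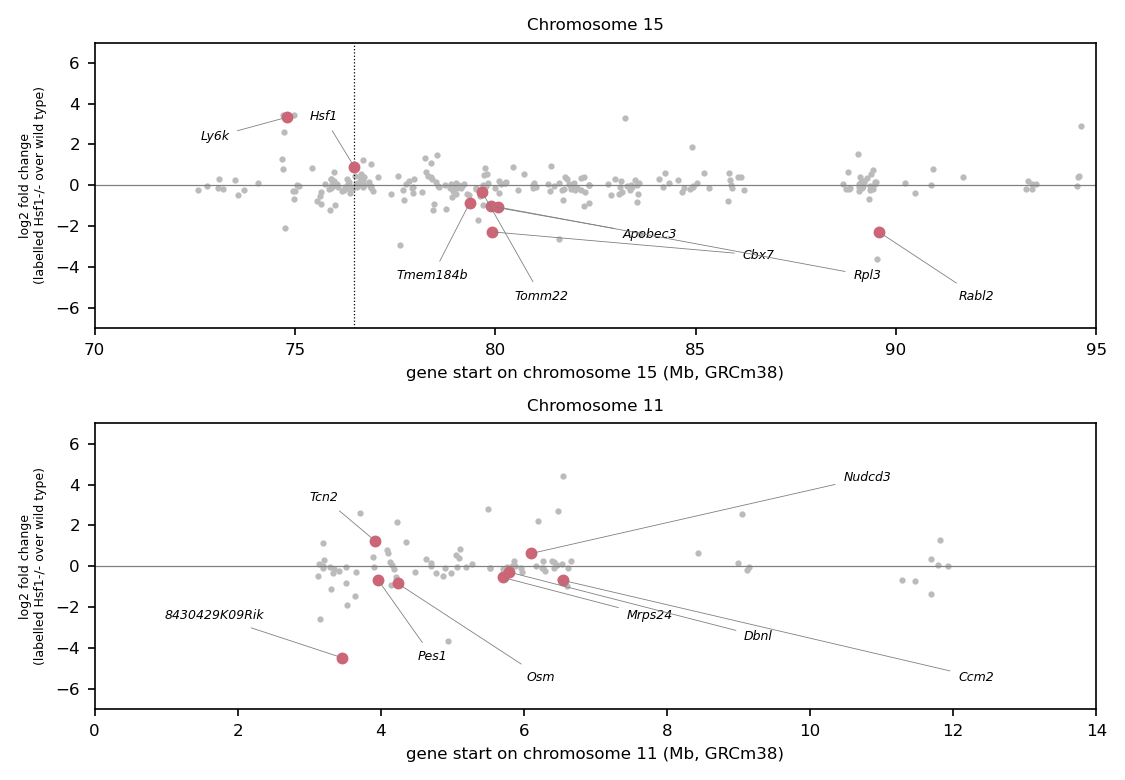
Genes tested along parts of chromosomes 15 and 11 of GRCm38 (position in Mb) against their log2 difference between cells labelled Hsf1-/- and wild-type cells averaged over treatments. Named points are the genes called at an adjusted p under 0.05, 8 on chromosome 15 and 8 in the first 10 Mb of chromosome 11, each with 2 higher and 6 lower.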

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

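The tests of Hspa1a, Bop1 and its sum with Hsf1, the 2 chromosome segments and the sum of Rpl3 and Rpl3-ps1 were chosen after the results were seen, and so was the form of the test of T cell receptor ratios. The test of the difference between genotypes picked out 1 list, the cytosolic ribosomal proteins, whose response to 17-AAG differed with an adjusted p of 0.0013 (27 of 40 positive), 0.959 with an estimated correlation. Without wild-type vehicle replicate 1, whose mean log2 score was 9.38 against 8.97 and 8.98 in replicates 2 and 3, it was 0.688.

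Hsf1 was counted 1.88-fold higher in the libraries labelled Hsf1-/-. An exchange of the genotype labels would place Hspa1a higher in these libraries, and it was lower by -3.64 (SE 0.54) on the log2 scale. Reads counted for Hsf1 instead of its neighbour Bop1 would lower Bop1 by as much as Hsf1 rose and keep the sum of both. Bop1 was at 198.7 ± 12.1 CPM in labelled and 217.6 ± 15.8 CPM in wild-type libraries (n = 6 each, log2 -0.13, SE 0.07). Hsf1 was at 139.7 ± 10.7 and 74.1 ± 6.10 CPM. The sum was 338 ± 21.1 and 292 ± 17.7 CPM, with overlapping ranges (303 to 360 and 272 to 323 CPM). These values argue against such reads as the source of the whole rise, and a part of it stays open. A gain of the whole region would raise the neighbours, and the 55 tested genes within 1 Mb had a median of -0.0190 (95% interval -0.10 to 0.09), with 0 called by edgeR. A transcript of the altered allele that is still counted may account for the higher value, which was not tested because counts per exon were not analysed here.

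Genes called by genotype lay close together on chromosomes 15 and 11. Strain variants in a segment inherited with the Hsf1 allele may account for the calls near Hsf1, since these were more frequent than elsewhere (8 of 307, Fisher's exact p = 0.000203). A segment apart from Hsf1 may do so on chromosome 11, where 8 calls lay in 10 Mb against a median of 3 for the fullest window in 10000 random draws (permutation p = 2e-04). By position the 2 segments do not hold all the calls, since 79.7% of the calls lay outside them. Effects of variants in these segments on genes elsewhere, and segments beyond these 2, were not tested. Reads moved from Rpl3 to Rpl3-ps1 do not account for the whole of the lower Rpl3, since the sum of both differed by -217 CPM (517 ± 100.4 in wild-type and 299 ± 35.1 in labelled libraries, n = 6 each). The sum covers only reads counted for either gene, and the treatment of reads that map to several places is not given. Effects of Hsf1 loss itself stay open, as the design joins them with linked variants.

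T and NK cell markers were lower under 17-AAG, a call that rests on the preset correlation (adjusted p = 0.179 with an estimated correlation, 0.196 by the rotation test fry). A lower share of T cells among the sorted cells needs their other abundant transcripts to be lower. It also needs their receptor genes to keep one ratio, but only if the other cells do not express these genes. The first held, with a median of -0.90 over 20 transcripts outside the list (95% interval -1.08 to -0.67). The second was not met: over 7 receptor genes the differences were unequal (exact permutation p = 0.005 over 400 arrangements, the smallest they can give). This counts against a lower share only under that condition, which was not tested. Trac over Cd3e was at 2.16 to 2.90 in the 6 vehicle and 3.40 to 8.52 in the 6 drug libraries. The ranges stood apart only for Trac or Trbc2 over Cd3d or Cd3e, and overlapped for every other pair. Trac over Trbc2, for instance, was at 1.63 to 2.17 with vehicle and 1.22 to 1.88 with the drug. A lower share of T cells therefore stays open and is not shown, since HSC expression of these genes was not measured apart, and so does an effect of 17-AAG on the transcripts. At the preset correlation no single library left out removed the averaged call, whose highest adjusted p was then 6.54e-08 (without wild-type vehicle replicate 1). Leaving out 1 library at a time cannot test extreme libraries in both arms together. The list score was highest in vehicle replicate 1 (3.98) and lowest in 17-AAG replicate 8 (0.510), both wild type.

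Other splits of the same libraries show what the grouping adds. For the genotype averaged over treatments 1 of 100 splits, the real one, called as many as the real 79, and the highest of the others called 0. This excludes chance there only if the vehicle and 17-AAG libraries are separate samples, which the labels do not state. For 17-AAG averaged over genotypes 100 of 100 splits called at least the real 0, the highest of the others 32, and for the interaction 100 of 100, the highest 41, which the real count of 0 fixes in advance, so these splits decide nothing for the edgeR counts (672 and 639 genes at an unadjusted p under 0.05; DESeq2 4 and 2, limma-voom 0 and 0). In comparisons of 3 libraries with 3, the 10 splits are too few for a share under 0.05. The numbers of splits with at least the real count were 10 for 17-AAG in wild-type cells (real 0, highest other 135), 10 in cells labelled Hsf1-/- (real 0, highest other 0), 1 for genotype under vehicle (real 16, highest other 0) and 1 under 17-AAG (real 13, highest other 0). The split with 135 calls set replicates 1, 7 and 8 against 2, 3 and 9, which points to a structure of the wild-type libraries other than treatment.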

How the results depend on the processing

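The term for Y-linked transcripts, leaving out 2 chromosome segments, and leaving out libraries for the list tests were chosen after seeing the data. No paired analysis was run because no label ties a vehicle to a 17-AAG library. The labels give each library its own number, and the groups share none. A pairing read from measured values was not fitted. If vehicle and 17-AAG libraries share animals, the averaged genotype tests count each animal more than once. The 17-AAG tests then keep differences between animals in their spread. DESeq2's size factors, upper-quartile scaling, limma-voom, and a stricter or no filter on low counts left each count of calls within 1.5 times, and no setting moved the median of all genes by over 0.1. Over all settings the list tests kept the side of the threshold in 2793 comparisons. The call was lost in 118, gained in 79 and turned in direction in 2. For named genes these numbers were 2189, 159, 7 and 0. Direction was compared only where the main setting or the alternative passed, so it can differ among uncalled comparisons. A missing adjusted p counted as no change.

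DESeq2 called 9 genes for 17-AAG in cells labelled Hsf1-/-, 4 for 17-AAG averaged, 2 for the interaction, and 106, 98 and 333 by genotype under vehicle, under 17-AAG and averaged. Its genotype calls include the 16, 13 and 79 of edgeR. The Y-linked term gave 148 in the average, 79 of them shared. Without the 2 segments 4, 3 and 43 genes were called. Of the 79 averaged calls 16 lie in the segments, so calls outside them were lost too. Under vehicle Cap1, Actb and Tgm2, which lie outside, had adjusted p of 0.0794, 0.0883 and 0.0610, with differences of -1.74, -0.46 and -0.93, and the cause was not tested. With only the groups compared 9 and 2 were called under vehicle and under 17-AAG, Hspa1a among the 9 as a call gained. This setting also reran the filter (13855 and 13828 genes tested), and the cause was not tested.

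With 1 library left out the count ranged from 6 to 10 under vehicle and 3 to 10 under 17-AAG. In the average it ranged from 34 to 101, with over 1.5 times fewer calls without replicates 2 (47), 3 (37), 4 (51), 5 (34), 6 (52), 9 (42), 10 (52) and 11 (37). The 17-AAG comparisons and the interaction stayed at 0 in edgeR.

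With an estimated correlation the T and NK cell list had an adjusted p of 0.539 in wild-type cells, 0.977 in cells labelled Hsf1-/- and 0.179 averaged. The HSF1 target, cholesterol and interferon lists had 0.473 each under vehicle, 0.338 each under 17-AAG and 0.260 each averaged, and the ribosomal list 0.959 for the interaction. A rotation test (fry) gave 0.538, 0.973 and 0.196 for the T and NK list. It gave 0.134, 0.198 and 0.198 under vehicle and 0.164, 0.239 and 0.239 under 17-AAG for HSF1 targets, cholesterol and interferon. Averaged by genotype, HSF1 targets kept their call at 0.0379, and cholesterol had 0.0692 and interferon 0.0566. For the interaction the ribosomal list had 0.969. The estimated correlation is the 1 change in the first of these tests, and the cause of the calls lost with fry was not tested.

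With 1 library left out, adjusted p of the T and NK list ranged from 7.66e-08 to 0.0545 in wild-type cells (highest without replicate 8), from 9.06e-08 to 0.000146 in cells labelled Hsf1-/- and from 1.36e-15 to 6.54e-08 averaged. HSF1 targets ranged from 0.00113 to 0.105 under vehicle, 0.00386 to 0.109 under 17-AAG and 0.000139 to 0.0147 averaged by genotype. Under 17-AAG they ranged from 0.683 to 0.990 in wild-type cells, 0.512 to 0.974 in cells labelled Hsf1-/-, 0.602 to 0.974 averaged and 0.703 to 0.986 for the interaction. Cholesterol ranged from 8.15e-14 to 0.000244, 1.12e-14 to 0.000367 and 1.18e-18 to 9.54e-12 by genotype, and interferon from 2.22e-24 to 1.76e-06, 4.09e-22 to 0.000104 and 1.64e-28 to 2.76e-13. The ribosomal list ranged from 5.4e-07 to 0.688 for the interaction. Under 17-AAG in wild-type cells the ribosomal list was called as higher without replicate 1 (0.0328) and as lower without 2 (0.00292), 3 (0.00197) and 7 (0.0270), with a highest value of 0.799. The first of these is a turn in direction, and so was the interferon list in cells labelled Hsf1-/- without replicate 12 (0.0167; range 0.00283 to 0.765), and the cause was not tested.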

Other observations

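Genes with very uneven levels between libraries of a group were noticed after the values were seen. Gm26825 was at 75.1, 101, 88.4 and 92.9 CPM in replicates 4, 5, 10 and 11 and at most 0.749 CPM in the other 8 libraries, among them replicates 6 and 12 of the same genotype label. Wdfy1 was at 5.197, 7.47, 6.75, 2.45, 6.29 and 4.18 CPM in replicates 1, 4, 5, 7, 10 and 11 and at 19.3 to 29.3 CPM in the others. Tdg, a thymine DNA glycosylase, was at 24.4, 46.6 and 52.9 CPM in replicates 1, 2 and 3, and at 74.2, 80.5 and 23.3 CPM in replicates 4, 5 and 6. It was at 18.8, 42.5 and 47.6 CPM in replicates 7, 8 and 9, and at 69.7, 64.5 and 24.8 CPM in replicates 10, 11 and 12.

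The labels tie no vehicle library to a 17-AAG library, and none were paired. Deviations from the group means over 6111 genes, compared between each vehicle and each 17-AAG library of a genotype, had correlations of 0.250 for replicates 1 and 7, 0.0938 for 2 and 8, 0.363 for 3 and 9, 0.346 for 4 and 10, 0.253 for 5 and 11 and 0.235 for 6 and 12. The other 12 combinations had -0.287 to 0.128. These combinations were singled out after the values were seen, and a shared origin of the cells was not tested.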
